A study of Mus musculus with 46 samples.

How the data were processed

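Gene expression was measured by sequencing of total RNA from the heart and striatum of adult mice, in 46 libraries: 22 from heart and 24 from striatum. The libraries were made with the CORALL V2 kit (Lexogen) from 1 ug of RNA. The mice were wild-type (WT) or carried the HrDR5 allele on both chromosomes, called mutant here. Each genotype had an untreated (euthyroid) group, a group given propylthiouracil (PTU) in low-iodine food for 15 days to cause hypothyroidism, and a group given PTU and then thyroid hormone (TH) for 24 hours, called PTU+TH here. Groups were read from the labels of genotype, tissue and treatment. Every group held 4 libraries except the untreated and the PTU hearts of mutant mice, which held 3 each. The label of 1 heart library, mutant PTU+TH replicate 1, gives the 15 days but not the 24 hours, and was kept in its group.

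The deposited files hold raw counts per gene, 1 library per file, with 57010 genes and 5 extra lines for reads given to no gene. The submitters' processing notes name Bowtie2, HTSeq and the mouse build GRCm39 without versions. The annotation release, the strand setting of the counting, trimming and the use of molecular identifiers are not given in the sources used here. Genes on opposite strands that overlap, such as Mhrt and Myh6, may therefore share counts. The reference at hand was GENCODE M21 on the older build GRCm38, which held 52029 of the 57010 gene identifiers. It was used only for the 49 genes within 1 Mb of Hr and for genes with exons on opposite strands that overlap by at least 50 bases, so no coordinates are given.

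Each tissue was fitted alone, with 1 coefficient per group, in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 14156 genes in heart and 15670 in striatum. Libraries were scaled by TMM factors, and groups were compared by the two-sided quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in a comparison. Changes are log2 fold changes with the standard error (SE) of the fitted coefficient. Levels are CPM, counts scaled to a common library total after TMM, with the standard deviation (SD) between libraries. In each tissue 11 comparisons were made: PTU, PTU+TH and untreated against each other within each genotype, mutant against WT at each treatment, and the genotype difference in the response to PTU and in the response to TH.

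The size of the mutant response relative to WT was the slope through the origin of mutant on WT log2 changes, over genes called for the average response of both genotypes. Its p came from an exact permutation of the genotype labels within each treatment, with 2450 relabelings in heart for TH and 1225 for PTU, and was two-sided. The position of a library on a WT change was its projection, over genes called for that change, on the line between the means of the 2 WT groups, from which a WT library's own value was left out; it was chosen after seeing the data. Ranges of WT libraries come from as many genes, taken first by p in the fit without the library placed, since genes chosen with a library favour its own end of the line. Genes reversed by TH in WT were those called in opposite directions by PTU and by TH. Both changes share the PTU libraries, so their overlap was set against the product of the 2 counts over the genes tested, against 20 simulations without a treatment effect, and against the 6 ways to give 2 of the PTU libraries to each change.

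Before the data were examined, 24 gene lists per tissue were fixed. Both tissues had lists of TH receptors, deiodinases, transporters and cofactors, the circadian clock, immediate early genes, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, cell division, the interferon response, blood cells, endothelial cells, macrophages and microglia, and Hr neighbours. Heart had lists of cardiac genes known to rise or to fall with TH, the fetal and stress programme, contraction and calcium handling, pacemaker and ion channels, fatty acid oxidation, glycolysis, extracellular matrix, atrial cardiomyocytes, smooth muscle and pericytes, adipocytes, and lymphocytes and thymus. Striatum had lists of brain genes known to rise or to fall with TH, projection neurons, interneurons, dopamine and glutamate signalling, myelin and oligodendrocytes, oligodendrocyte progenitors, astrocytes, cortical excitatory neurons, choroid plexus and ependyma, meninges and fibroblasts, and synaptic plasticity and neurofilaments. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list. Counts of members called are given over all genes tested and adjusted over the list alone.

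The genes named were set by a rule fixed with the lists. It takes Hr, up to 8 called genes with the largest rise and up to 8 with the largest fall per comparison, up to 4 called members per list, and called neighbours of Hr. The largest changes needed a mean of at least 1 CPM and, between 2 groups, no overlap of their libraries. Predicted genes were left out. Genes of the rule are named from the start of each order.

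Replicates of a group differed by more than counting noise in every pair, and no pair of files was identical. The replicate numbers did not pair libraries: over the 51 same-number pairs in heart the mean residual correlation was 0.066, and over the 60 in striatum it was 0.042. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples. Library shares were compared with exact permutation tests, adjusted over the 54 tests of a tissue, where 4 against 4 libraries cannot give a p below 0.0286 and 3 against 3 cannot reach 0.05. Counts of 0 are set against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% interval. Floors and intervals cover counting error only.

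The fits were tested on simulated counts of the same depth and spread. With a log2 change of 1 in 99 genes, 60.6% were called for WT TH against PTU in heart and 62.6% in striatum. At a log2 change of 2 these shares were 92.9% and 93.0%. For the genotype difference in TH response they were 16.0% and 54.0% at 1, and 72.0% and 83.0% at 2. False calls numbered 4 to 15 per comparison. A simulated relative size of 0.5 was returned as 0.545 in heart and 0.507 in striatum, and a size of 1 as 1.016 and 1.009 with p = 0.0506 and 0.0278 by exact permutation, so an unchanged size can reach such a p. Of the lists given a change 20 of 20 were called in each tissue, and of those left unchanged 0 of 20. Simulated genes varied independently, so the error of the list test under correlation between genes was not tested.

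The alternatives fixed in advance were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, each library left out in turn, genes selected in 1 genotype for the sizes, and limma fry for the lists. Alternatives chosen after seeing the data were a covariate for the reads given to no gene, a sex covariate from Xist and Ddx3y, the 15 striatum libraries with more unassigned reads alone, 2 mutant striatum libraries left out, and list tests with that covariate or without those libraries, heart mutant untreated replicate 2 or striatum mutant PTU+TH replicate 4.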

Results

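The series asked whether a deletion of 1 nucleotide at the mouse hairless gene, Hr, changes the response of Hr and of other genes to thyroid hormone (TH). RNA was counted in 46 libraries from heart and striatum of wild-type (WT) and mutant (HrDR5/DR5) mice that were untreated, hypothyroid after 15 days of propylthiouracil (PTU), or given TH for 24 hours after PTU (PTU+TH). There were 4 libraries per group, and 3 for the hearts of untreated and of PTU-treated mutant mice. Gene counts per library ran from 3.27 to 19.53 M counts in heart and from 9.469 to 13.66 M counts in striatum. The lowest total belonged to heart mutant untreated replicate 2, and the next lowest in heart was 8.235 M counts.

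Hr (ENSMUSG00000022096), which encodes a nuclear corepressor, followed TH in WT hearts. It stood at 15.9 ± 0.426 CPM in untreated WT hearts, 2.19 ± 1.03 in PTU hearts and 75.7 ± 5.66 in PTU+TH hearts (SD, n = 4 each). In mutant hearts it stood at 9.10 ± 8.50 CPM untreated (n = 3), 2.51 ± 1.02 with PTU (n = 3) and 16.2 ± 3.15 with PTU+TH (n = 4). Hr fell by 2.88 ± 0.359 on the log2 scale with PTU in WT hearts (adjusted p = 2.34e-05) and rose by 5.13 ± 0.378 with TH (adjusted p = 3.36e-09). In mutant hearts it fell by 1.97 ± 0.436 with PTU (adjusted p = 0.00949) and rose by 2.68 ± 0.409 with TH (adjusted p = 0.00215). After TH, Hr was lower in mutant than in WT hearts by a log2 change of -2.22 ± 0.321 (adjusted p = 0.00675), and the levels of the 4 mutant and 4 WT libraries did not overlap. The genotype difference in the TH response of Hr was -2.45 ± 0.533 (adjusted p = 0.0459). The genotypes were not shown to differ untreated (log2 change -0.68 ± 0.363, adjusted p = 0.839) or with PTU (0.23 ± 0.430, adjusted p = 0.818), and the difference in PTU response was 0.92 ± 0.562 (adjusted p = 0.431). The call after TH was lost without mutant PTU+TH replicate 1 (adjusted p = 0.0631) or replicate 3 (adjusted p = 0.0578), with fold changes of -2.23 and -2.22. The call for the TH response held only without WT PTU replicate 4 or mutant PTU replicate 3, and leaving out any other library of the 4 groups gave an adjusted p of 0.0559 to 0.518. It was also lost with the replicate number as a block (-2.50, adjusted p = 0.0514). The fall in mutant hearts was not called without mutant untreated replicate 3 (-0.86, adjusted p = 0.159) or mutant PTU replicate 2 (-2.02, adjusted p = 0.054). Without mutant untreated replicate 3, Hr was called lower in untreated mutant hearts (-1.79, adjusted p = 0.0416).

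In WT striatum Hr stood at 20.8 ± 11.9 CPM untreated, 11.2 ± 2.79 with PTU and 33.1 ± 9.62 with PTU+TH (SD, n = 4 each). In mutant striatum it stood at 15.6 ± 2.48, 15.4 ± 3.23 and 18.5 ± 11.7 CPM in the same order (SD, n = 4 each). No comparison of Hr in striatum passed the test. The log2 change with TH was 1.56 ± 0.367 in WT (adjusted p = 0.0516) and 0.27 ± 0.362 in mutant (adjusted p = 0.965), and the difference between them was -1.29 ± 0.513 (adjusted p = 0.753). The WT change was called without WT PTU+TH replicate 3 (1.73, adjusted p = 0.0216) and with DESeq2 (adjusted p = 0.00376). The change with PTU was -0.88 ± 0.368 in WT (adjusted p = 0.599) and -0.02 ± 0.366 in mutant (adjusted p = 0.988). Mutant against WT gave -0.41 untreated (adjusted p = 1), 0.45 with PTU (adjusted p = 1) and -0.84 after TH (adjusted p = 1).

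**Figure D1:**
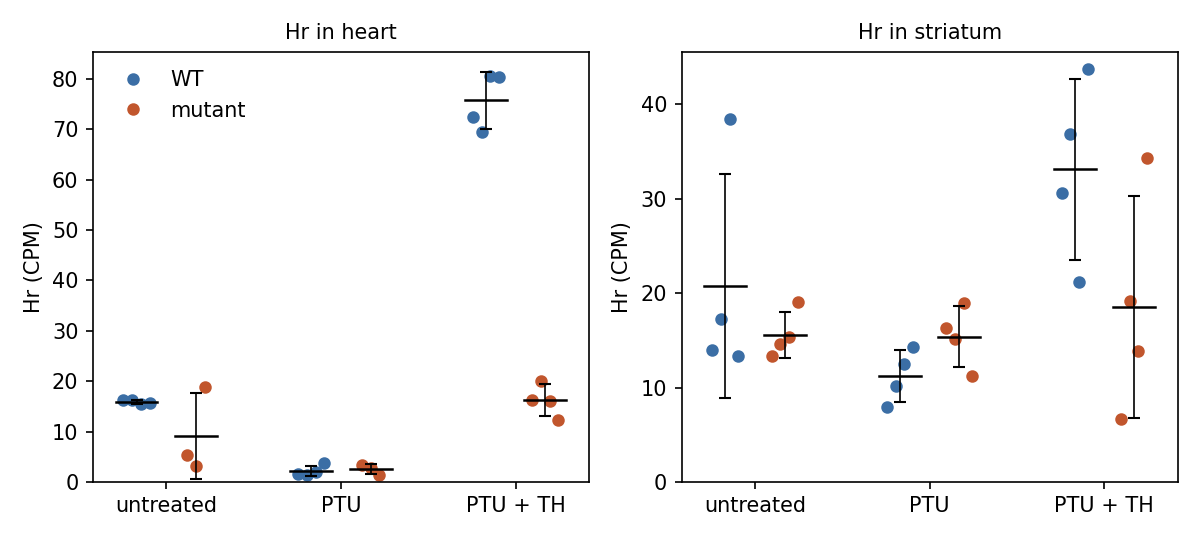
Level of Hr in CPM in each heart and striatum library by genotype and treatment, with points for libraries and bars for the mean and SD. In heart after TH, WT libraries averaged 75.7 CPM and mutant libraries 16.2 CPM.

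The first heart comparison asked what PTU changed in WT. The hearts exchanged their myosin heavy chains: Myh6, the fast alpha isoform, fell from 22040 ± 9629 to 170 ± 215 CPM, and Myh7, the slow beta isoform, rose from 165 ± 93.4 to 19410 ± 8053 CPM (SD, n = 4 each). On the log2 scale Myh6 fell by 7.02 ± 0.730 (adjusted p = 2.4e-06) and Myh7 rose by 6.88 ± 0.491 (adjusted p = 1.48e-08). Tnni1, the slow skeletal troponin I, rose by 6.13 ± 0.808, and the relaxin receptor gene Rxfp1 rose by 4.23 ± 1.08. Tmem232, Rtl3, Lrrc52, Lpar3 and Cib3 rose by 2.52 to 4.23. Klhl33, Tlcd2, Ankrd35 and the chemokine gene Cxcl14 fell, with log2 changes of -4.18 to -2.90. The antisense genes Foxo6os and Mhrt fell by 3.89 and 3.65, with counts that may include the opposite strand.

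Lists fixed beforehand moved in WT PTU hearts. Of 15 genes known to rise with TH in heart, 7 fell and none rose (8 adjusted over the list alone), among them the pacemaker channel gene Hcn2 (-2.74 ± 0.263), the uncoupling protein gene Ucp3 (-2.16 ± 0.424) and Klf9 (-1.20 ± 0.338), a TH-responsive transcription factor gene (adjusted p = 1.97e-09, and adjusted p = 0.0148 with an estimated correlation). Of 9 genes known to fall with TH, 3 rose (3 adjusted over the list alone), which were Myh7, the potassium channel subunit gene Kcne1 (1.88 ± 0.319) and the sodium-calcium exchanger gene Slc8a1 (1.02 ± 0.215), with adjusted p = 3.7e-05 and adjusted p = 0.0403 with an estimated correlation. Of 21 interferon response genes, 11 fell (13 adjusted over the list alone), led by Isg15 (-1.90), Gbp3 (-1.77), Ifit3 (-1.41) and Rsad2 (-1.37), with adjusted p = 1.71e-11 and adjusted p = 0.0386 with an estimated correlation. With the share of unassigned reads as a covariate, chosen after seeing the data, and an estimated correlation, neither the interferon list (adjusted p = 0.0692) nor the list known to fall with TH (adjusted p = 0.0715) passed. Of 9 blood cell genes 4 fell (8 adjusted over the list alone; adjusted p = 3.75e-06, and adjusted p = 0.219 with an estimated correlation), led by the anion exchanger gene Slc4a1 (-3.06 ± 0.754). Haemoglobin genes took 0.0549% of the counts in these hearts and 0.185% in untreated WT hearts (exact permutation p = 0.0286, adjusted p = 0.386). Of 20 cell division genes 4 fell and 1 rose (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.000214, and adjusted p = 0.125 with an estimated correlation). Top2a fell by 2.26 while Cenpf rose by 2.17. Of 19 macrophage genes 3 fell (6 adjusted over the list alone; adjusted p = 1.49e-06, and adjusted p = 0.0691 with an estimated correlation), led by C1qc (-1.02). Of 17 immediate early genes Fosb, Arc and Fos fell (6 adjusted over the list alone; adjusted p = 0.000436, and adjusted p = 0.355 with an estimated correlation). Of 30 fatty acid oxidation genes 4 fell and Ppargc1a rose (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.3 with an estimated correlation). Of 29 matrix genes 3 fell (7 adjusted over the list alone; adjusted p = 0.000766, and adjusted p = 0.409 with an estimated correlation), led by Col15a1 (-1.07). None of 41 oxidative phosphorylation genes was called over all genes or over the list alone, with a median log2 change of -0.35 (adjusted p = 1.02e-05, and adjusted p = 0.591 with an estimated correlation).

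In total 694 of 14156 genes were called with PTU in WT hearts, 266 higher and 428 lower. The count was 1069 without WT PTU replicate 1, in which Myh7 stood at 7457 CPM against 21950 to 24790 CPM in the other 3 libraries. It was 483 to 1069 over all fits that left out 1 library.

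TH for 24 hours raised Myh6 in WT hearts to 24450 ± 2760 CPM, a log2 rise of 7.17 ± 0.735 (adjusted p = 4.93e-07), and lowered Myh7 to 5529 ± 884 CPM, a log2 fall that came to -1.81 ± 0.391 (adjusted p = 0.00281; SD, n = 4). Rgs7, a regulator of G protein signalling, rose by 6.45 ± 0.425 (adjusted p = 7.74e-10), the fucosyltransferase gene Fut2 by 5.95 ± 0.663, Tlcd2 by 5.45 ± 0.394 and the antisense gene Foxo6os by 5.91 ± 0.397. Some risen genes were almost silent with PTU. Prss55 had 0 counts over the 4 WT PTU hearts and 3.83 ± 0.980 CPM after TH (SD, n = 4), at least 84.3-fold higher against a floor of 3 counts over the group (adjusted p = 2.84e-07). Lrat, which encodes a retinol acyltransferase, had 1 count over the 4 WT PTU hearts and 1145 after TH, a ratio of 1420 (exact 95% interval 254 to 56100), and Lypd8l had 3 and 2411 counts, a ratio of 997 (341 to 4840). Rtl3, Tmem232, Lrrc52, Cenpf, Lpar3 and Crb1 fell, with log2 changes of -4.43 to -3.02. Ighm, the immunoglobulin mu heavy chain, rose from 3.77 ± 0.656 to 76.4 ± 11.6 CPM, a log2 rise of 4.33 ± 0.220 (adjusted p = 1.03e-11).

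Of the 15 genes known to rise with TH in heart, 8 rose (9 adjusted over the list alone), among them Ucp3 (3.33 ± 0.439), Hcn2 (3.15 ± 0.266) and the beta-1 adrenergic receptor gene Adrb1 (1.40 ± 0.227), with adjusted p = 1.72e-08 and adjusted p = 0.0204 with an estimated correlation. Of the 9 known to fall, 3 fell and Thrb rose (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.0237, and adjusted p = 0.359 with an estimated correlation). Of 17 immediate early genes Arc, Egr1 and Fosl2 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0298, and adjusted p = 0.995 with an estimated correlation). The lymphocyte list had 2 members tested, of which Ighm rose (1 adjusted over the list alone; adjusted p = 0.00865, and adjusted p = 0.0837 with an estimated correlation). Of 24 tested neighbours of Hr, Nudt18 (2.23 ± 0.235), Fhip2b (0.79) and Reep4 (0.71) rose and Bin3 (-0.79) fell (adjusted p = 0.229 for the list, and adjusted p = 0.995 with an estimated correlation).

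The remaining heart lists did not pass the list test for TH against PTU in WT, with adjusted p from 0.0901 to 0.993 and 0.995 with an estimated correlation, and their members went both ways or were few. Among 15 TH receptors, deiodinases, transporters and cofactors, the receptor gene Thra fell (-0.84) and Slc16a10 (0.70) and Thrb (0.67) rose. Of 22 cholesterol synthesis genes 3 rose and 2 fell, of 30 fatty acid oxidation genes 3 rose and 3 fell, of 17 glycolysis genes 2 rose and 3 fell, and of 21 pacemaker and channel genes 3 rose and 3 fell. Acta1 (2.06), Acta2 (1.54) and Actc1 (1.36) rose among 12 genes of the fetal and stress programme, and Jph2 rose and Myom2 fell among 20 genes of contraction and calcium handling. Of 29 matrix genes 3 rose, of 19 macrophage genes 2, of 21 interferon genes 1 (Gbp3, 1.11) and of 12 smooth muscle genes 1 (Acta2), and of 20 cell division genes Mcm2 rose and Cenpf fell. None of 18 circadian, 41 oxidative phosphorylation, 13 mitochondrially encoded, 9 blood cell, 15 endothelial, 10 atrial or 9 adipocyte genes was called. The list-alone counts differed from these for cholesterol synthesis (4 rose and 2 fell), fatty acid oxidation (6 and 3), glycolysis (3 and 3), channels (4 and 4), contraction (2 and 2), the fetal programme (3 and 1) and TH receptors (2 and 2).

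In total 1614 genes were called with TH in WT hearts, 823 higher and 791 lower. Of these, 467 had been called in the opposite direction with PTU (190 that rose and then fell and 277 that fell and then rose), against 14.9 and 24.9 if the calls were independent, and none had been called in the same direction. In 20 simulations without a treatment effect at most 1 gene was called per change, so their overlap of 0 sets no bound. With 2 PTU libraries used for each change and none for both, 159 to 264 genes were shared against 10.9 to 18.1 under independence.

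Compared with untreated WT hearts, those given TH kept Myh7 higher by 5.07 ± 0.451 (adjusted p = 6.27e-07) and Tnni1 higher by 4.33 ± 0.855. Genes above their untreated level included Lrat (4.54 ± 0.600), Lypd8l (4.05), Ttbk1 (3.94), Rgs7 (3.73), Ighm (3.50 ± 0.211, adjusted p = 4.17e-10), the nicotinamide riboside kinase gene Nmrk2 (2.66) and Hr (2.25 ± 0.321, adjusted p = 0.000262). Retreg1, Stum, Cntn5, Retnla, Art5 and the class II antigen gene H2-Eb1 were lower by log2 changes of -2.02 to -1.77. The lymphocyte list passed through Ighm (1 of 2 rose, 1 adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.0324 with an estimated correlation). Of 21 interferon genes 5 fell (10 adjusted over the list alone; adjusted p = 4.12e-09, and adjusted p = 0.0864 with an estimated correlation). Cell division, macrophage, oxidative phosphorylation, blood cell and fatty acid oxidation lists moved down with adjusted p of 1.71e-07 to 0.00772, and adjusted p = 0.209 to 0.624 with an estimated correlation. In total 288 genes were called, 142 higher and 146 lower. DESeq2 called 518, no filter 575, and the count was 177 without WT untreated replicate 4, 128, 121 and 154 without WT PTU+TH replicates 2, 3 and 4.

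**Figure D2:**
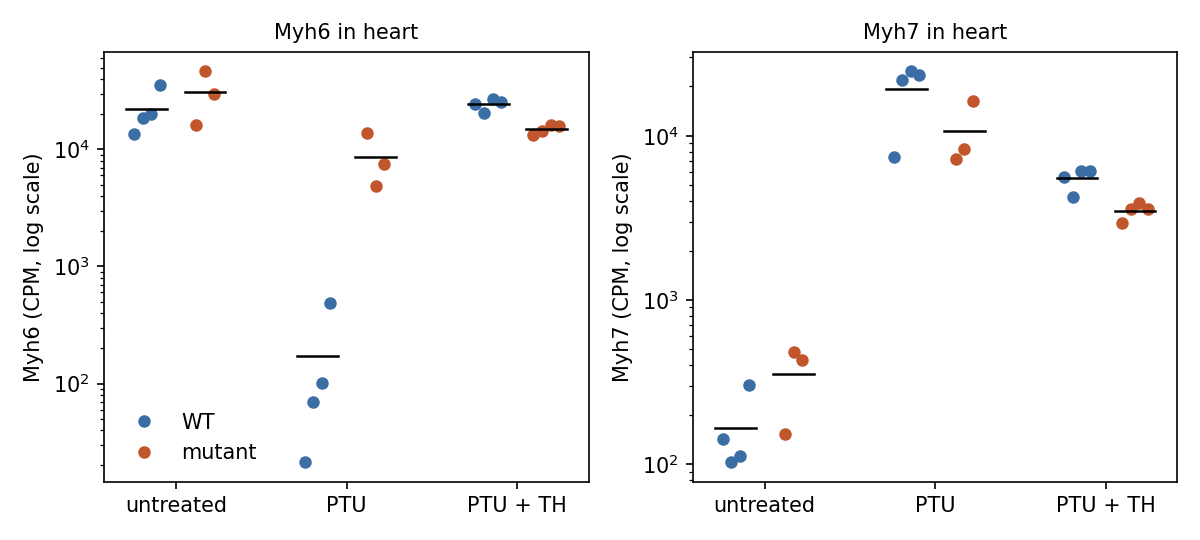
Levels of Myh6 and Myh7 in each heart library by genotype and treatment, in CPM on a log axis, with points for libraries and lines for group means. With PTU, Myh6 averaged 170 CPM in WT and 8687 CPM in mutant hearts.

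In mutant hearts PTU raised Myh7 from 356 ± 178 to 10620 ± 4930 CPM, while Myh6 stood at 30760 ± 15330 CPM untreated and 8687 ± 4543 with PTU (SD, n = 3 each). The log2 change of Myh6 was -1.82 ± 0.668 and did not pass the test (adjusted p = 0.0674). Myh7 rose by 4.90 ± 0.517 (adjusted p = 3.1e-05), Rxfp1 by 4.67 ± 1.37, Tnni1 by 3.49 ± 1.08, Tmem232 by 2.97 and the orphan receptor gene Nr4a3 by 2.80. The chemokine receptor gene Cx3cr1 fell by 3.69 ± 0.698, Rassf10 by 2.81 and Ankrd35 by 2.58. Mitochondrial mt-Nd6 fell by 7.14 ± 1.24, from 33550 ± 56080 to 237 ± 11.3 CPM, and its untreated mean rested on replicate 2 at 98300 CPM. Of 9 genes known to fall with TH, 5 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.0246, and adjusted p = 0.342 with an estimated correlation). Of 21 interferon genes 9 fell (15 adjusted over the list alone; adjusted p = 3.06e-07, and adjusted p = 0.161 with an estimated correlation), led by Oas1a (-2.10) and Irf7 (-1.81). Of 19 macrophage genes 8 fell (12 fell and 1 rose adjusted over the list alone; adjusted p = 2.93e-05) and of 20 cell division genes 7 fell (7 adjusted over the list alone; adjusted p = 0.000119), each with adjusted p = 0.161 with an estimated correlation. The other lists past the preset test moved down with adjusted p of 0.00311 to 0.0479, and adjusted p = 0.343 to 0.666 with an estimated correlation: oxidative phosphorylation, blood cells, endothelial cells, fatty acid oxidation, matrix, smooth muscle and Hr neighbours. Of these, blood cells and Hr neighbours did not pass without mutant untreated replicate 2 (adjusted p = 0.0901 and 0.173). In total 1952 genes were called, 884 higher and 1068 lower. This count rested on single libraries: it was 85 without mutant untreated replicate 2, 3163 without replicate 1 and 831 without replicate 3, and 1153, 115 and 666 without mutant PTU replicates 1, 2 and 3.

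TH raised Ighm in mutant hearts from 4.12 ± 1.28 (n = 3) to 77.9 ± 17.3 CPM (SD, n = 4), a log2 rise of 4.23 ± 0.251 (adjusted p = 3.07e-10). Lypd8l rose by 4.25 ± 0.547, Tmem52 by 2.92, Prss55 by 2.85, Lrat by 2.78 ± 0.569, Ttbk1 by 2.63 and Tlcd2 by 2.51 ± 0.357. Myh6 was not called (0.78 ± 0.617, adjusted p = 0.963). The Hr neighbour Nudt18 rose by 1.65 ± 0.256 (adjusted p = 0.00224). Cenpf fell by 2.34, Lad1 by 2.16, the desaturase gene Scd4 by 1.96, the apolipoprotein gene Apod by 1.45 and the phosphodiesterase gene Pde1c by 1.25 ± 0.186. Of the 15 genes known to rise with TH, Hcn2 (1.52 ± 0.278) and the sodium pump subunit gene Atp1b1 (0.82 ± 0.149) rose (2 adjusted over the list alone; adjusted p = 0.000687, and adjusted p = 0.156 with an estimated correlation). Of the 9 known to fall, 0 fell (2 adjusted over the list alone; adjusted p = 0.000687, and adjusted p = 0.135 with an estimated correlation). The lymphocyte list passed through Ighm (1 of 2 rose, 1 adjusted over the list alone; adjusted p = 4.7e-07, and adjusted p = 0.00238 with an estimated correlation). Of 20 cell division genes only Cenpf was called, against a list median of 0.52 (1 rose and 1 fell adjusted over the list alone; adjusted p = 0.000687, and adjusted p = 0.187 with an estimated correlation), and 0 of 21 interferon genes were called over all genes or over the list alone (median 0.22; adjusted p = 0.0122, and adjusted p = 0.755 with an estimated correlation). In total 58 genes were called, 38 higher and 20 lower, and all 58 were called in the same direction in WT, where 2.21 and 1.12 were due under independence. DESeq2 called 133 and no filter 151. The count was 106, 16 and 15 without mutant PTU replicates 1, 2 and 3, and 35 without mutant PTU+TH replicate 2; the shared count was 104, 16, 15 and 35.

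Against untreated mutant hearts, those given TH had higher Lypd8l (5.04 ± 0.610), Lrat (4.72 ± 0.726), Ttbk1 (3.70), Shisa6 (3.45), Ighm (3.44 ± 0.245), Myh7 (3.30 ± 0.468), Rgs7 (3.27) and the transferrin receptor gene Tfrc (3.13). Cx3cr1 (-3.50 ± 0.614), the phospholipase gene Pla2g2d (-3.17), Oscp1 (-3.03) and Trim12c (-2.79) were lower. Hr was 0.71 ± 0.363 higher without passing the test (adjusted p = 0.16). Interferon (9 of 21 fell, 14 adjusted over the list alone; adjusted p = 0.000517) and macrophage genes (9 of 19 fell and 1 rose, 10 and 1 adjusted over the list alone; adjusted p = 0.00191) both had adjusted p = 0.345 with an estimated correlation. Oxidative phosphorylation, cell division, endothelial and smooth muscle lists moved down and the lymphocyte list up with adjusted p of 0.0307 to 0.0442, and adjusted p = 0.345 to 0.752 with an estimated correlation. The cell division and lymphocyte calls were lost without mutant untreated replicate 2 (adjusted p = 0.071 each). In total 3118 genes were called, 1515 higher and 1603 lower. The count was 1173 without mutant untreated replicate 2, 1819 without mutant untreated replicate 3 and 2042 without mutant PTU+TH replicate 2.

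Mutant and WT hearts were then compared at each treatment. With PTU, mutant hearts had more Myh6 (5.67 ± 0.699, adjusted p = 6.96e-05), with 8687 ± 4543 (n = 3) against 170 ± 215 CPM (SD, n = 4). The antisense gene Foxo6os (4.32 ± 0.419), Rgs7 (4.06 ± 0.468), Rp1 (4.03), Klhl33 (3.70) and the Nogo receptor gene Rtn4r (3.28 ± 0.506) were higher too. Lrat, with 1 count over the WT PTU hearts, had 139 over the mutant PTU hearts, a ratio of 306 (exact 95% interval 54.1 to 12200), and Lypd8l had 3 and 139, a ratio of 102 (34.2 to 501). Tubb2b (-2.10), Lrrc52 (-1.91), Rtl3 (-1.86), Lad1 (-1.73), Scx (-1.56) and Hook2 (-1.55) were lower. Of the 15 genes known to rise with TH, 5 were higher in mutant PTU hearts (9 adjusted over the list alone), among them Ucp3 (1.72) and Hcn2 (1.18), with adjusted p = 3.62e-06 and adjusted p = 0.0731 with an estimated correlation. The 6 lower genes named, Ucp3 and Hcn2 each lost their call in at least 1 fit that left out a single library. Cell division and glycolysis lists were lower (adjusted p = 0.0337, and adjusted p = 0.894 with an estimated correlation). In total 311 genes were called with PTU, 219 higher and 92 lower, while DESeq2 called 550 and no filter 482. The count was 199 and 154 without WT PTU replicates 2 and 3, and 78, 121 and 196 without mutant PTU replicates 1, 2 and 3. Mitochondrially encoded genes took 42.7% of the counts in mutant and 33.1% in WT PTU hearts (exact permutation p = 0.0286, adjusted p = 0.386).

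After TH only 2 genes differed between mutant and WT hearts by edgeR: Hr was lower, and Cpox, a haem synthesis enzyme gene, was higher by 0.89 ± 0.147 (adjusted p = 0.0265), at 61.7 ± 4.99 against 33.4 ± 6.80 CPM (SD, n = 4 each). At an unadjusted p below 0.05 there were 1764 genes against 708 due by chance, while DESeq2 called 132 and no filter 39. Without mutant PTU+TH replicate 1 or 3 no gene was called, and 1 was called without WT PTU+TH replicate 1, 2 or 3 or mutant PTU+TH replicate 2. The call of Cpox was lost in each of these 6 fits (adjusted p of 0.0578 to 0.217). Glycolysis, smooth muscle and Hr neighbour lists were lower in mutant hearts (adjusted p = 0.0367, 0.0367 and 0.0474, and adjusted p = 0.724, 0.597 and 0.597 with an estimated correlation). Untreated, edgeR called 0 genes, with 823 at an unadjusted p below 0.05 (708 due by chance) and a smallest adjusted p of 0.0898. DESeq2 called 4 and no filter 127, and the count was 21 without mutant untreated replicate 1 and 12 without replicate 3. Immediate early genes were lower in untreated mutant hearts (4 of 17 adjusted over the list alone) and macrophage (1 of 19 adjusted over the list alone), endothelial, smooth muscle and circadian lists higher, with adjusted p of 0.00539 to 0.0467, and adjusted p = 0.733 to 0.791 with an estimated correlation. The smooth muscle call was lost without mutant untreated replicate 2 (adjusted p = 0.0546).

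The genotypes were next compared for their responses. The TH response of Myh6 was smaller in mutant hearts by a log2 difference of -6.38 ± 0.878 (adjusted p = 0.000721). Foxo6os (-4.19 ± 0.510), Rgs7 (-3.96 ± 0.558), Rtn4r (-3.65 ± 0.643) and Klhl33 (-3.56 ± 0.653) also had smaller responses in mutant hearts, and Rnf122 (1.65 ± 0.325) and Tmem164 (1.40 ± 0.286) differed the other way. Myh6, Foxo6os and Rgs7 kept their calls in every fit that left out 1 library, while Rtn4r, Klhl33, Rnf122 and Tmem164 each lost it in at least 1. Of the 15 genes known to rise with TH, Myh6 alone was called (5 adjusted over the list alone), and the list had a median difference of -0.42 (adjusted p = 8.99e-09, and adjusted p = 0.0177 with an estimated correlation). In total 41 genes were called, 2 higher and 39 lower. Of these, 40 differed more between genotypes at PTU than at PTU+TH, 40 were called between genotypes at PTU, and 1, Hr, was called at PTU+TH. DESeq2 called 87 and no filter 136, and the count at an unadjusted p below 0.05 was 632 against 708 due by chance. It was 24, 17 and 68 without WT PTU replicates 1, 3 and 4, 26 and 27 without WT PTU+TH replicates 2 and 3, 11 without mutant PTU replicate 1, and 25 and 26 without mutant PTU+TH replicates 3 and 4.

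The PTU response of mutant hearts differed for Myh6 by 5.19 ± 0.914 (adjusted p = 0.0123), a call lost without mutant untreated replicate 3 (5.17, adjusted p = 0.0511) or mutant PTU replicate 1 (4.71, adjusted p = 0.0664). It differed for Foxo6os (4.65 ± 0.563), Rtn4r (3.94 ± 0.721), Shisa6 (3.66 ± 0.767), Rgs7 (3.50 ± 0.652) and Tlcd2 (3.19 ± 0.594) in the same direction. The metallothionein gene Mt2 (-1.90 ± 0.411), Hook2 (-1.87), the lipoxygenase gene Alox12 (-1.74), Mical1 (-1.74) and Rabep2 (-1.72) differed the other way. Of the genes named for this difference, Foxo6os alone kept its call in every fit that left out 1 library. Of the 15 genes known to rise with TH, Myh6 alone was called (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.931 with an estimated correlation). In total 82 genes were called, 68 higher and 14 lower, of which 74 were called between genotypes at PTU, 0 untreated, and 26 also for the TH response. DESeq2 called 297 and no filter 341. Without mutant PTU replicate 1 the count was 1, and without mutant untreated replicates 1, 2 and 3 it was 721, 35 and 4. It was 35 without mutant PTU replicate 2, 39, 53 and 127 without WT untreated replicates 2, 3 and 4, and 37 and 36 without WT PTU replicates 2 and 3.

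Over the 1647 genes called for the average TH response in heart, the mutant response was 0.524 of the WT response (exact permutation p = 0.00735). It was 0.478 over genes called in WT (p = 0.000816) and 0.622 over genes called in mutant (p = 0.02), both by the same exact permutation. On the axis from WT PTU at 0 to WT PTU+TH at 1, over genes called in WT, mutant hearts averaged 0.515 with PTU (WT 0.024). With PTU+TH they averaged 0.959 (WT 0.982). The lower ratio thus went with the level at PTU rather than with the level after TH. Over the 2666 genes called for the average PTU response the ratio was 1.269 (exact permutation p = 0.396), and it lay on either side of 1 with the genes chosen: 0.582 over genes called in WT (exact permutation p = 0.0229) and 2.088 over genes called in mutant (exact permutation p = 0.0269). It was 0.952 without mutant untreated replicate 2 and 1.888 without replicate 1.

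In WT striatum TH after PTU raised Fgf16, a growth factor gene, by 4.23 ± 0.627 (adjusted p = 0.00831), from 0.224 ± 0.074 to 4.31 ± 1.51 CPM, and Gkn3 by 4.16 ± 0.761, from 0.186 ± 0.163 to 3.67 ± 1.66 CPM (SD, n = 4 each). Cyp2s1 (3.45), Cd72 (3.32), Ace (3.29 ± 0.599), which encodes angiotensin-converting enzyme, Il17rc (2.30), Gbp3 (2.00) and the receptor gene Gpr139 (1.83) rose. The transporter gene Slc4a11 (-1.78 ± 0.342), Rtl9 (-1.08), Arhgap6 (-0.95), Pkp2 (-0.94), Zkscan16 (-0.88) and the cold-inducible Cirbp (-0.77 ± 0.164) fell. Of 18 genes known to rise with TH in brain, 3 rose (11 adjusted over the list alone): the semaphorin gene Sema7a (1.46 ± 0.270), neurogranin, Nrgn (1.10 ± 0.197), and the astrocyte potassium channel gene Kcnj10 (1.04 ± 0.230), with adjusted p = 2.67e-08 and adjusted p = 0.137 with an estimated correlation. Of 10 genes known to fall, Cirbp fell (1 adjusted over the list alone; adjusted p = 0.0311, and adjusted p = 0.625 with an estimated correlation). Plasticity and neurofilament genes (Nrgn of 18 rose, 4 adjusted over the list alone; adjusted p = 0.00157), cholesterol synthesis (0 of 23 called, 0 adjusted over the list alone; adjusted p = 0.00157), oxidative phosphorylation (0 of 41, 1 adjusted over the list alone; adjusted p = 1.73e-08) and interferon genes (Gbp3 of 19 rose, 2 adjusted over the list alone; adjusted p = 0.0311) all had adjusted p = 0.625 with an estimated correlation. With the share of unassigned reads as a covariate the interferon list did not pass (adjusted p = 0.0515). The Hr neighbour Dmtn, of 22 tested, rose by 0.79 ± 0.171 (adjusted p = 0.324 for the list). In total 72 of 15670 genes were called, 60 higher and 12 lower, with 1990 at an unadjusted p below 0.05 against 784 due by chance. DESeq2 called 320 and no filter 257. The count was 0 without WT PTU replicate 1, 2 or 3, 31 without WT PTU replicate 4, 1 without WT PTU+TH replicate 1, 2 or 4, and 357 without WT PTU+TH replicate 3. Reads given to no gene divided the striatum libraries into samples with more (15) and with fewer (9), and with that share as a covariate, chosen after seeing the data, the count was 222, against 0 within the 15 samples with more.

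The other striatum lists did not pass the test for TH against PTU in WT (adjusted p from 0.13 to 0.98) and had no member called over all genes: 18 TH receptors, deiodinases, transporters and cofactors (1 rose adjusted over the list alone), 18 circadian, 19 immediate early, 8 mitochondrially encoded, 25 cell division, 8 blood cell, 15 endothelial, 18 macrophage and microglia, 25 projection neuron, 16 interneuron (1 rose adjusted over the list alone), 20 dopamine and glutamate (3 rose adjusted over the list alone), 18 myelin, 9 oligodendrocyte progenitor, 16 astrocyte (1 fell adjusted over the list alone), 14 cortical, 10 choroid plexus and 12 meningeal genes.

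No gene was called in the other striatum comparisons by edgeR. Sema7a stood at 122 ± 19.1, 49.4 ± 7.61 and 136 ± 13.7 CPM in WT untreated, PTU and PTU+TH striatum, and at 126 ± 19.1, 92.3 ± 33.6 and 107 ± 45.7 CPM in mutant striatum (SD, n = 4 each). Nrgn stood at 1959 ± 157, 970 ± 106 and 2079 ± 168 CPM in WT, and at 2072 ± 160, 1375 ± 408 and 1523 ± 554 CPM in mutant. In each striatum comparison 784 genes were due by chance at an unadjusted p below 0.05. For PTU against untreated in WT there were 1179, DESeq2 called 34 and no filter 82, and 1 was called without WT untreated replicate 2. In the same comparison 8 of 18 genes known to rise with TH in brain were lower adjusted over the list alone (adjusted p = 1.87e-09, and adjusted p = 0.0844 with an estimated correlation). Cholesterol synthesis (adjusted p = 2.29e-11, and adjusted p = 0.171 with an estimated correlation), oxidative phosphorylation (adjusted p = 9.05e-06), myelin (adjusted p = 0.00296), plasticity (adjusted p = 0.00734), cell division (adjusted p = 0.00734), interferon (adjusted p = 0.0118) and blood cell lists (adjusted p = 0.0383) were lower as well. Endothelial genes (adjusted p = 0.019) and genes known to fall with TH in brain (adjusted p = 0.0304) were higher, and all these but cholesterol synthesis had adjusted p = 0.482 to 0.563 with an estimated correlation. The blood cell list did not pass with the unassigned-read covariate (adjusted p = 0.13). No gene was called as reversed by TH in WT striatum by edgeR, against 32 by DESeq2 and 75 with no filter, and 1 was called without WT untreated replicate 2 or WT PTU+TH replicate 3. For TH against untreated in WT 235 genes, below the number due by chance, had an unadjusted p below 0.05 and DESeq2 called 0. Lists passed the preset test there without a member called over all genes or over the list alone: myelin (adjusted p = 0.000131), cholesterol synthesis (adjusted p = 0.000186), cell division (adjusted p = 0.00759), circadian (adjusted p = 0.0224) and blood cell lists (adjusted p = 0.0314) were lower, and endothelial (adjusted p = 0.000131) and oxidative phosphorylation lists (adjusted p = 0.00493) higher. With an estimated correlation the endothelial list had adjusted p = 0.116 and the others adjusted p = 0.815 to 0.915, and with the unassigned-read covariate the circadian (adjusted p = 0.112) and oxidative phosphorylation lists (adjusted p = 0.205) did not pass.

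In mutant striatum 1578 genes had an unadjusted p below 0.05 for PTU against untreated, 359 for TH against PTU and 705 for TH against untreated, against 784 due by chance, and DESeq2 called 0 in each. A single gene was called for PTU without mutant untreated replicate 2, and for TH against untreated without mutant PTU+TH replicate 3. Genes known to rise with TH in brain had a median log2 change of -0.33 with PTU (0 of 18 adjusted over the list alone; adjusted p = 0.00329, and adjusted p = 0.384 with an estimated correlation). This fall was 1 of many with PTU: oxidative phosphorylation (adjusted p = 3.57e-12), cholesterol synthesis (adjusted p = 1.55e-09), projection neuron (adjusted p = 4.98e-07), immediate early and blood cell (adjusted p = 0.000759 each), microglia and astrocyte (adjusted p = 0.00329 each), interferon (adjusted p = 0.00568), myelin (adjusted p = 0.00604), cell division (adjusted p = 0.00665), plasticity (adjusted p = 0.019), interneuron (adjusted p = 0.0192), mitochondrially encoded and choroid plexus lists (adjusted p = 0.0343 each) were lower too, with adjusted p = 0.384 to 0.444 with an estimated correlation, and no list that passed was higher. With the unassigned-read covariate the microglia, astrocyte, myelin, plasticity, interneuron and choroid plexus lists did not pass (adjusted p = 0.237 to 0.7). Without mutant PTU replicate 1 and mutant PTU+TH replicate 1 the mitochondrially encoded, cell division, myelin and choroid plexus lists did not (adjusted p = 0.0967 to 0.203).

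For TH against PTU in mutant striatum oxidative phosphorylation (adjusted p = 0.000316), myelin (adjusted p = 0.00381), astrocyte (adjusted p = 0.00749), immediate early (adjusted p = 0.0163) and cholesterol synthesis lists (adjusted p = 0.0299) were higher, and mitochondrially encoded (adjusted p = 0.00183) and dopamine and glutamate lists (adjusted p = 0.0211) lower, each with adjusted p = 0.725 with an estimated correlation. Of these the mitochondrially encoded list alone passed with the unassigned-read covariate. For TH against untreated in mutant, mitochondrially encoded (5 of 8 adjusted over the list alone) and projection neuron (adjusted p = 9.62e-09 each), cholesterol synthesis (adjusted p = 3.82e-08), oxidative phosphorylation (adjusted p = 4.92e-07), blood cell (adjusted p = 1.95e-05), microglia (adjusted p = 0.00031), circadian (adjusted p = 0.000405), dopamine and glutamate (adjusted p = 0.00562) and interneuron lists (adjusted p = 0.0101) were lower, with adjusted p = 0.171 to 0.405 with an estimated correlation. The interneuron list did not pass with the covariate (adjusted p = 0.112) or without mutant PTU+TH replicate 4 (adjusted p = 0.119), nor the oxidative phosphorylation list with the covariate and without the 2 libraries (adjusted p = 0.0793). No gene was shared between the TH responses of the genotypes.

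Between mutant and WT striatum 339 genes had an unadjusted p below 0.05 untreated, 714 with PTU and 544 after TH, all below the 784 due by chance, and DESeq2 called 0, 2 and 1. Untreated, oxidative phosphorylation (adjusted p = 6.62e-09), mitochondrially encoded and cholesterol synthesis (adjusted p = 0.00208 each), plasticity (adjusted p = 0.0152) and microglia lists (adjusted p = 0.0471) were higher in mutant, with adjusted p = 0.723 to 0.844 with an estimated correlation, and the last 3 did not pass with the covariate (adjusted p = 0.286 to 0.86). With PTU, genes known to rise with TH in brain were higher in mutant (2 of 18 adjusted over the list alone; adjusted p = 3.02e-05, and adjusted p = 0.306 with an estimated correlation). That group held replicate 1, which stood at 0.943 on the axis from WT PTU at 0 to WT PTU+TH at 1. Without it and mutant PTU+TH replicate 1, left out after seeing the data, the list median was 0.32 (adjusted p = 0.000633, and adjusted p = 0.304 with an estimated correlation). In the same comparison cortical genes were higher (median 0.80, 0 of 14 called or called over the list alone; adjusted p = 0.00237) and projection neuron genes lower (median -0.15, 0 of 25; adjusted p = 0.000377), each with adjusted p = 0.567 with an estimated correlation. Cholesterol synthesis (adjusted p = 0.0048) and plasticity lists (adjusted p = 0.00687) were higher too, and immediate early (adjusted p = 0.004) and TH receptor lists (adjusted p = 0.0498) lower, with adjusted p = 0.306 to 0.567 with an estimated correlation, and the TH receptor list did not pass with the covariate (adjusted p = 0.0639). After TH, dopamine and glutamate signalling genes were lower in mutant with a median of -0.13 (0 of 20 called, 0 adjusted over the list alone; adjusted p = 1.11e-05, and adjusted p = 0.0398 with an estimated correlation). Without the same 2 libraries this was adjusted p = 3.85e-06, and adjusted p = 0.066 with an estimated correlation. Without mutant PTU+TH replicate 4, in which Prkcd, a thalamic marker, stood at 108 CPM, it was adjusted p = 0.00423, and adjusted p = 0.448 with an estimated correlation. In the same comparison myelin genes were higher (median 0.27; adjusted p = 4.92e-07), and projection neuron (median -0.12; adjusted p = 4.92e-07) and mitochondrially encoded genes (median -0.25; adjusted p = 0.000733) lower, each with adjusted p = 0.628 with an estimated correlation. Oxidative phosphorylation genes were lower as well (adjusted p = 0.0315, and adjusted p = 0.797 with an estimated correlation). Neither they (adjusted p = 0.0818, and adjusted p = 0.124 with the covariate instead) nor the projection neuron list (adjusted p = 0.45) passed without mutant PTU+TH replicate 4. The genotype difference in response had 352 genes at an unadjusted p below 0.05 for PTU, where DESeq2 called 0, and 920 for TH (784 due by chance in each), where DESeq2 called 6 and edgeR called 3 without mutant PTU replicate 4. For PTU, the difference was positive for genes known to rise with TH in brain (median 0.30, 0 of 18 adjusted over the list alone; adjusted p = 0.0293) and negative for genes known to fall (median -0.16; adjusted p = 0.0118), projection neuron (adjusted p = 0.00063), oxidative phosphorylation (adjusted p = 0.0118) and mitochondrially encoded genes (adjusted p = 0.0383), with adjusted p = 0.532 to 0.718 with an estimated correlation. Without the 2 libraries neither list of TH genes nor the mitochondrially encoded list passed (adjusted p = 0.0993 each), and with the covariate the oxidative phosphorylation list did not (adjusted p = 0.994). For TH, 4 of 18 genes known to rise with TH in brain responded less in mutant adjusted over the list alone (adjusted p = 0.00019, and adjusted p = 0.741 with an estimated correlation). Without the 2 libraries it was adjusted p = 0.0334, and adjusted p = 0.0668 with the unassigned-read covariate as well.

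No gene was called for the average TH response of the genotypes in striatum, so the planned relative size had no value. Over the 72 genes called in WT, which favours WT and tests no difference, the mutant response was 0.058 of the WT response. It was 0.238 without mutant PTU replicate 1 and 0.284 without mutant PTU+TH replicate 1. These libraries stood on the axis from WT PTU at 0 to WT PTU+TH at 1 at the level of the other group. Without both, left out after seeing the data and because of their values, it was 0.434, again no test. Other single omissions gave -0.099 (mutant PTU replicate 4) to 0.085, or no value for most WT PTU and PTU+TH libraries. For PTU in striatum 7 genes were called for the average response, with a relative size of 0.565 and too few genes for a test.

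**Figure D3:**
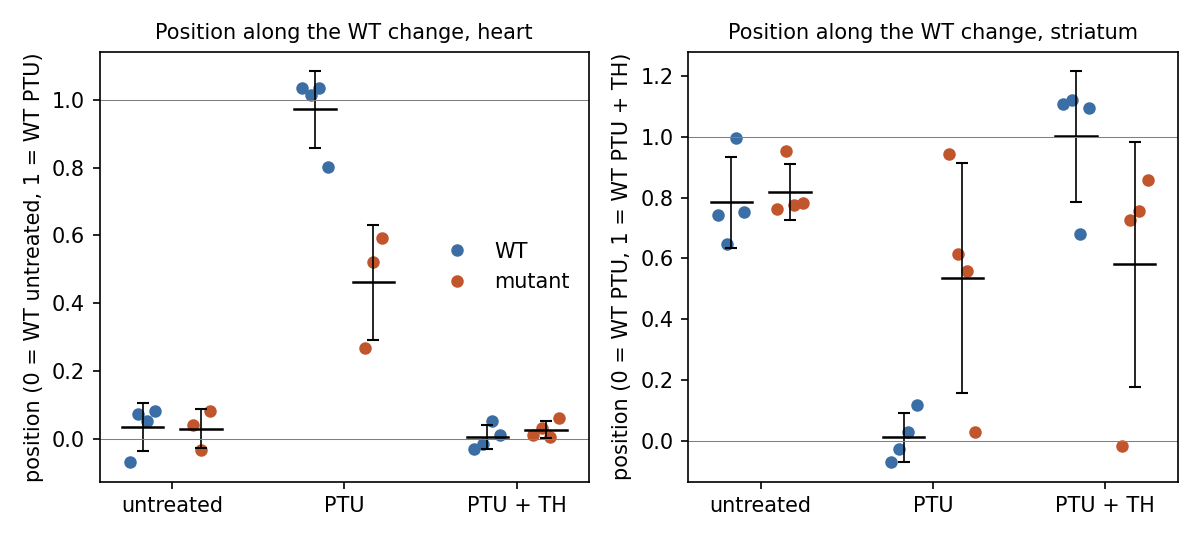
Position of each library on the axis of WT changes, in units of the WT change, for the PTU change in heart (0, WT untreated; 1, WT PTU) and the TH change in striatum (0, WT PTU; 1, WT PTU+TH), with points for libraries and bars for the mean and SD. Mutant PTU hearts averaged 0.461 and WT PTU hearts 0.972 on the PTU axis.

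**Figure D4:**
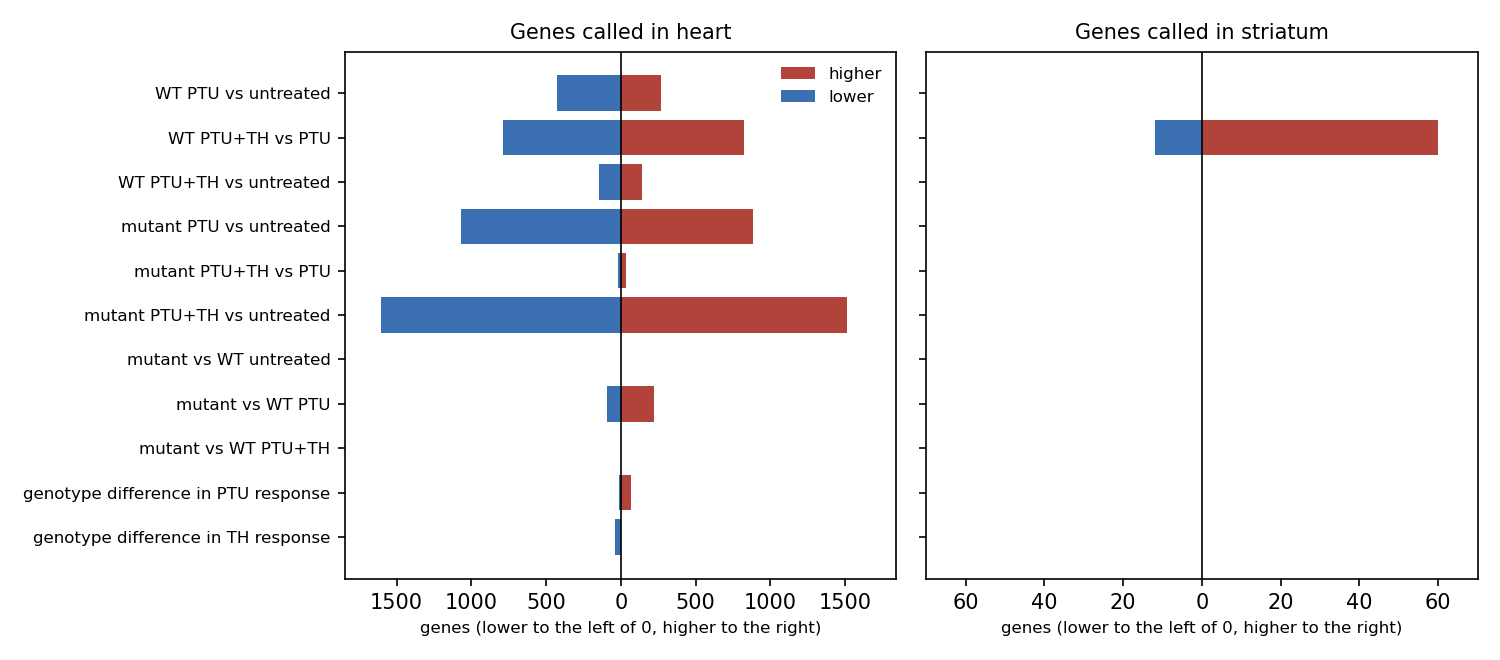
Number of genes called at an adjusted p below 0.05 in each comparison, higher and lower, in heart and striatum, on x axes that differ between the panels. WT hearts had 1614 genes called for TH against PTU, and mutant hearts 58.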

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

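Of the tests below, those of mislabelling, atrial tissue, milder hypothyroidism, cortex (both tests), unassigned reads and strand loss, and all library positions, were chosen after the results were seen, while the splits of the samples and the test of low depth were set before.

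The hearts of mutant mice given PTU lay between untreated and hypothyroid WT hearts, at 0.461 ± 0.17 (SD, n = 3) on the axis from untreated WT at 0 to WT PTU at 1, where WT PTU hearts averaged 0.972 ± 0.113 (SD, n = 4). A single wrong label would displace 1 library, but 3 of the 3 mutant PTU hearts lay below the 0.739 to 0.973 of WT PTU hearts placed over genes chosen without them. Atrial tissue in replicates 1 and 2 is argued against, since 0 of 2 carried more Myl7, an atrial transcript, than every WT PTU heart. Replicate 3 (259 CPM) stayed at 0.541 over 474 genes, against 0.789 to 1.054 in WT PTU hearts, too close to decide. These differ by under 0.3 (log2) between Myl7-rich WT PTU+TH replicate 3 and the other 3. Milder hypothyroidism of the mutant PTU animals could also give this pattern. Over 18 brain genes known to rise with TH, 3 of the 4 mutant PTU striata lay above the WT PTU range, set by females only. Replicate 1, doubted below, was among them. With the trend with cortical genes, higher in this group (median 0.80), taken out, 3 still did. An allele effect in both tissues would do the same, so these cannot be told apart without hormone levels. An effect of the allele on the PTU response beyond Hr stays open as a hypothesis.

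In striatum, mutant PTU replicate 1 stood at 0.943 and mutant PTU+TH replicate 1 at -0.015 on the axis from WT PTU at 0 to WT PTU+TH at 1, each at the level of the other group. A swap of the labels of these libraries is a candidate explanation, as 2 of the 2 lay within or beyond the range of the WT libraries of the other group placed over genes chosen without them (0.006 to 0.276 for PTU and 0.558 to 1.054 for PTU+TH), although mutant PTU replicates 2 and 3, at 0.616 and 0.558, reached the latter range too. Different amounts of cortex are argued against: 3 untreated libraries with as little Slc17a7 as mutant PTU+TH replicate 1 (66.8 CPM or less) lay at 0.741 or above, and mutant PTU replicate 1 (132 CPM) lay within the 70.7 to 188 CPM of the other mutant PTU libraries. The share of reads outside genes is also argued against, since the distance between the 2 libraries was 0.959 and stayed at 0.946 once the trend with that share over the other 22 libraries, a median shift of 0.23 (log2) per gene over its range, was taken out. A biological difference between these animals was not tested, and the groups were left as labelled.

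Heart mutant untreated replicate 2 held 3.27 M gene counts and 46.0 unassigned reads per 100 gene reads, with mt-Nd6 at 98300 CPM. Genes opposite a more abundant gene shifted by a median of 0.152 (log2), with other hearts up to 0.153. Their overlaps may be short, so loss of strand information stays undecided. Low depth alone is argued against: 95 genes stood at 4 times or more their mean over the other hearts. Other hearts thinned to the same total had at most 39 (WT PTU replicate 1) and a median of 6. No biological explanation was tested, and what set this library apart stays open.

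Single libraries far from the other 3 of their group numbered 10 of 72 groups tested, where chance gives about 1 in 20. Hr stood at 38.43 CPM in striatum WT untreated replicate 3 against 13.37 to 17.25 CPM. Myh7 stood at 7457 CPM in heart WT PTU replicate 1 against 21950 to 24790 CPM. Heart WT untreated replicate 3 held 19.53 M counts against 10.53 to 11.78 M. Haemoglobin genes took 0.1852% of heart WT PTU+TH replicate 1 against 0.04976% to 0.06793%. Unassigned reads per 100 gene reads were 5.705 in striatum WT untreated replicate 4 against 12.76 to 14.16, and 15.53 in mutant untreated replicate 2 against 5.746 to 6.515. The position on the heart PTU axis was 0.803 in WT PTU replicate 4 against 1.014 to 1.036. On the striatum TH axis it was 0.68 in WT PTU+TH replicate 3 against 1.094 to 1.121, 0.953 in mutant untreated replicate 2 against 0.762 to 0.783, and -0.015 in mutant PTU+TH replicate 1 against 0.727 to 0.857.

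Responses that differed between the genotypes by a test of the difference were counted as 82 heart genes for PTU and 41 for TH. The relative size of the TH response was 0.524 in heart over genes called for the average response. Mutant hearts were close to WT after TH (0.959 against 0.982 on the WT TH axis). In striatum the relative size was 0.058 over genes called in WT, a choice that favours WT, so this value is no test of the difference. The striatum value was 0.238 without mutant PTU replicate 1, 0.284 without mutant PTU+TH replicate 1, 0.434 without both, and -0.099, -0.007, 0.002, -0.051 and 0.022 without mutant PTU replicate 4, mutant PTU+TH replicates 2, 3 and 4 and WT PTU replicate 4. For PTU in heart the genes with a log2 difference were Mt2 (-1.90), Hook2 (-1.87), Alox12 (-1.74), Mical1 (-1.74), Rabep2 (-1.72), Tlcd2 (3.19), Rgs7 (3.50), Shisa6 (3.66), Rtn4r (3.94), Foxo6os (4.65), Myh6 (5.19), Lypd8l (6.43) and Lrat (7.11). For TH they were Lrat (-6.93), Myh6 (-6.38), Prss55 (-5.73), Lypd8l (-5.43), Foxo6os (-4.19), Rgs7 (-3.96), Rtn4r (-3.65), Klhl33 (-3.56), Hr (-2.45), Tmem164 (1.40) and Rnf122 (1.65). The fitted values of Lrat, Lypd8l and Prss55 rest on 0 to 3 counts over the WT PTU hearts and depend on the prior count of the fit. For TH, the call of Lrat was lost without WT PTU replicate 1 or 3 or mutant PTU replicate 1 (adjusted p up to 0.163), and that of Lypd8l without WT PTU replicate 1, 2 or 3 or mutant PTU replicate 1 (up to 0.314). The call of Prss55 for TH was lost without WT PTU replicate 1, 2 or 3, any WT PTU+TH library, mutant PTU replicate 1 or mutant PTU+TH replicate 2, 3 or 4 (up to 0.691). For PTU, the call of Lrat was lost without WT untreated replicate 2, WT PTU replicate 1, 2 or 3, mutant untreated replicate 2 or 3 or mutant PTU replicate 1 (up to 0.136), and that of Lypd8l without mutant untreated replicate 3 or mutant PTU replicate 1 (up to 0.0748). The cardiac genes known to rise with TH had a median difference of -0.42 in the TH response.

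Other splits of the same libraries set how far chance can be excluded. In heart, 1 of 35 splits gave as many genes as the real one for WT TH against PTU (1614, highest other 5), WT TH against untreated (288, highest other 1), mutant TH against PTU (58, highest other 1), mutant TH against untreated (3118, highest other 689), mutant against WT with PTU (311, highest other 134) and mutant against WT after TH (2, highest other 0). For the difference in TH response 1 of 100 splits gave 41 (highest other 38). For that in PTU response 3 of 100 gave 82 or more, and the highest other of 1618 points to a structure of the samples other than the groups. These shares are not adjusted over the 11 comparisons of a tissue, and 35 splits can give no share below 1 of 35. Chance is thus made less likely for these counts but not excluded. For mutant PTU against untreated the 10 splits are too few (1952, 1 split, highest other 1). For WT PTU against untreated 4 of 35 splits gave 694 or more, so chance is not excluded for this count. The highest, 1943, exchanged untreated replicate 3 with PTU replicate 1 and put all females together, so sex may be a factor. With no PTU library used for both changes, 159 to 264 genes moved in opposite directions with PTU and with TH, against 10.9 to 18.1 under independence. That reference takes genes to vary independently. A structure shared by the PTU samples could also give this overlap, so it does not exclude chance either. Untreated mutant and WT hearts gave 0 genes, which any split equals (35 of 35), so the splits test nothing there. The highest of these, 1033, followed sex but for mutant replicate 3, while 27 other splits gave 0.

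In striatum chance cannot be excluded for WT TH against PTU, where 2 of 35 splits gave 72 or more. The highest other, 302, set PTU replicate 2 and PTU+TH replicates 1, 2 and 4 against the rest, which follows the samples with few unassigned reads except for replicate 4, and with that share as a covariate the real split called 222. Where the real split gave 0 genes any split equals it (35 of 35), so the splits test nothing, and the highest other was 0 for WT PTU against untreated, WT TH against untreated, mutant PTU against untreated, mutant TH against untreated and mutant against WT with PTU, 4 for mutant TH against PTU and 1 for mutant against WT after TH. The highest other for untreated mutant against WT was 1226, in the split that exactly follows the unassigned reads, and with the covariate the real split called 0. The differences in response to PTU and TH gave 0 genes, which 100 of 100 splits equal by construction, with highest others of 730 and 3381, the latter in a split that follows unassigned reads for the PTU+TH libraries but not for the PTU ones. Counts several times the real one point to a structure of the striatum samples.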

How the results depend on the processing

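The covariates, the set of 15 striatum libraries, the omission of 2 mutant striatum libraries and the list tests with omitted libraries were chosen after the results were seen; all other alternatives were fixed in advance. No call of a named gene or of Hr changed direction, but 1 list did: myelin genes for mutant PTU against untreated striatum, with the covariate and without the 2 libraries (adjusted p = 0.284, and adjusted p = 0.805 with an estimated correlation). Relative sizes crossed 1 or 0 as well: that of the heart PTU response is given below, and that of the striatum TH response became -0.099, -0.007 and -0.051 without mutant PTU replicate 4 and mutant PTU+TH replicates 2 and 4. RLE size factors kept every heart count within 1.5 times. The replicate block, although replicate numbers pair no samples, moved no count by over 1.5 times and ended the call of Hr for the heart TH response (-2.50, adjusted p = 0.0514). The cause of the changes below was not tested, except that omissions leave fewer samples. Low counts limit the genes tested, and the shallow heart mutant untreated replicate 2 limits all contrasts with that group. The relative size over genes called in WT striatum has no value in settings that called fewer than 20 genes. For the named genes, leaving out 1 library kept 2836 results, weakened 568, strengthened 18 and moved 22, DESeq2 kept 369, weakened 5 and strengthened 17, and no filter kept 353, weakened 14, strengthened 26 and moved 2. For the lists, the estimated correlation kept 402 and weakened 126, fry kept 422, weakened 104 and strengthened 2, and the unassigned-read covariate kept 492, weakened 26 and strengthened 10.

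Without a filter the heart counts were 575 (WT TH against untreated), 151 (mutant TH against PTU), 127, 482 and 39 (mutant against WT untreated, PTU and PTU+TH), 341 and 136 (differences in PTU and TH response) and 132 (shared TH response). With DESeq2 they were 518, 133, 4, 550, 132, 297, 87 and 132. In striatum no filter gave 82 (WT PTU against untreated), 257 (WT TH against PTU), 3 and 8 (mutant PTU and PTU+TH against untreated), 5 and 6 (mutant against WT with PTU and PTU+TH), 24 (difference in TH response) and 75 (reversal). DESeq2 gave 34, 320, 2 (mutant against WT with PTU), 1 (PTU+TH), 6 and 32. The sex covariate gave 1 for WT PTU against untreated and for the reversal. The unassigned-read covariate gave 222 for WT TH against PTU, and 0 in the set with more such reads alone. Mutant against WT after TH gave 1 with RLE, with that covariate, and with it and without the 2 libraries. Hr in striatum with TH in WT was called with no filter (1.58), DESeq2 (1.56), the unassigned-read covariate (1.68) and the sex covariate (1.74), with adjusted p from 9.15e-05 to 0.0322. The relative size of the heart PTU response became 0.582 over genes selected in WT and 2.088 over those in mutant.

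Leaving out each library in turn, heart counts ran from 483 to 1069 (WT PTU against untreated), 121 to 302 (WT TH against untreated), 85 to 3163, 15 to 106 and 1173 to 3902 (mutant PTU against untreated, TH against PTU, TH against untreated), 0 to 21, 78 to 324 and 0 to 3 (mutant against WT untreated, PTU, PTU+TH), 1 to 721 and 11 to 68 (differences in PTU and TH response) and 15 to 104 (shared TH response). Hr ran from -2.29 to -0.86 (heart mutant PTU against untreated), -1.79 to -0.36 (mutant against WT untreated), -2.34 to -2.11 (after TH), -2.80 to -2.16 (difference in TH response) and, in striatum WT with TH, 1.38 to 1.73. In striatum counts ran from 0 to 357 (WT TH against PTU), 0 to 3 (difference in TH response) and 0 to 1 for WT PTU against untreated, mutant PTU against untreated, mutant TH against untreated and the reversal.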

Other observations

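The levels of single genes and the sex of the libraries were looked up after the results were seen, while the lists were fixed before. The immunoglobulin gene Ighm and the Hr neighbour Nudt18 responded to TH in hearts of both genotypes. Ighm stood at 6.78 ± 1.16, 3.77 ± 0.656 and 76.4 ± 11.6 CPM in WT untreated, PTU and PTU+TH hearts (SD, n = 4 each), and at 77.9 ± 17.3 CPM in mutant PTU+TH hearts (SD, n = 4). Nudt18 stood at 21.2 ± 2.34 CPM in WT and 24.3 ± 3.22 CPM in mutant PTU+TH hearts (SD, n = 4 each), and at 4.48 ± 0.882 (n = 4) and 7.66 ± 3.76 CPM (n = 3) with PTU. In the other tissue Ighm stood at 7.86 ± 0.580 CPM in WT PTU striatum and 23.3 ± 8.49 CPM in WT PTU+TH striatum (SD, n = 4 each), without passing the test.

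In striatum, the cholesterol synthesis list was lower with PTU in both genotypes by the preset test, and none of its genes passed over all genes. Other lists fell with it, among them myelin genes in both genotypes (adjusted p = 0.00296 in WT and adjusted p = 0.00604 in mutant) and, in mutant, projection neuron (adjusted p = 4.98e-07), astrocyte and microglia genes (adjusted p = 0.00329 each), and none of these passed with an estimated correlation (adjusted p = 0.384 to 0.563). In WT 9 of 23 were lower adjusted over the list alone, with a median log2 change of -0.35 (adjusted p = 2.29e-11, and adjusted p = 0.171 with an estimated correlation). In mutant 9 of 23 were lower adjusted over the list alone, with a median of -0.38 (adjusted p = 1.55e-09, and adjusted p = 0.384 with an estimated correlation). With the share of unassigned reads as a covariate, chosen after seeing the data, the medians were -0.30 in WT (adjusted p = 3.67e-10, and adjusted p = 0.194 with an estimated correlation) and -0.21 in mutant (adjusted p = 9.31e-08, and adjusted p = 0.336 with an estimated correlation). In mutant that share went largely with PTU: 4 of the 4 PTU libraries and 1 of the 4 untreated ones were among the samples with more such reads.

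Some libraries held markers of nearby tissue. Myl7 stood at 259, 274 and 181 CPM in heart mutant PTU replicate 3, WT PTU+TH replicate 3 and mutant PTU+TH replicate 4. Striatum mutant PTU+TH replicate 4 held Prkcd and Calb2 at 108 and Slc17a6 at 114 CPM. By Xist and Ddx3y, females numbered 4 in WT PTU striatum, 2 in other striatum groups, 2 in untreated and 1 in other heart groups. Animals thus partly differed. Sex partly confounds WT PTU contrasts in striatum and those with untreated in heart.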
